A study of Mus musculus with 18 samples.

How the data were processed

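RNA was measured in macrophages sorted by flow cytometry from the spleen, bone marrow and large intestine of mice without a fluorescent transgene that shared their circulation, by parabiosis, with DsRed-transgenic mice. Macrophages that carried DsRed are called engulfing here and those without it non-engulfing. Each tissue gave 3 sample pairs of 1 engulfing and 1 non-engulfing library, so that there are 18 libraries in 6 groups of 3. Per the labels' protocols, 2 ng of starting material was amplified with a kit for single cells, libraries of polyA RNA followed in 2 batches, and the labels number the pairs 1 to 9. Batch 1 holds 12 libraries (6 pairs) and batch 2 holds 6 libraries (3 pairs, replicate 4 of every tissue), and both members of a pair share a batch. The labels do not say whether different pairs come from different animals, so the p-values of genes in the engulfing comparisons measure the spread between sample pairs. Those of the tissue comparisons measure the spread between libraries. The p-values of gene lists at a preset correlation mainly set the genes of a list against the other genes.

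Per the labels' protocols, the authors used CASAVA 1.8.2, cutadapt and RSEM 1.2.3 with the mouse build GRCm38. The table deposited by the authors holds 1 signal value per gene and library for 14215 Ensembl gene identifiers, and its gene filter and normalization are not given in the sources used here. In each library 100% of the deposited signal values above 0 were whole multiples of 1 step (tolerance 0.01). Dividing by that step gave recovered reads, 4.31 to 40.8 M per library. The scaling of the deposited signal divided by edgeR's TMM factors of the recovered reads gave 0.996 to 1.00. Symbols and coordinates came from GENCODE M21, which is on the build named in the labels: 14005 identifiers had a symbol and 210 had none. Amplified reads are not independent molecules, so intervals from read numbers cover counting error only.

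Because the table holds scaled values and not counts, the test used is limma's moderated test (R 4.3.3, limma 3.58.1, eBayes with trend) on log2(value + 1), the choice foreseen for scaled values, in place of edgeR's test foreseen for counts. For the engulfing comparisons, 1 fit over the 18 libraries had the sample pair as a block and an engulfing effect per tissue (6 residual degrees of freedom). It gave the effect in each tissue, the mean of the 3 effects and a test of their difference between tissues. The 3 tissue comparisons used the 9 non-engulfing libraries with the library batch as a term (5 residual degrees of freedom). All 14215 genes were tested, with no further filter, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are given with their standard error, and group values as mean signal ± SD with n = 3 libraries. The pairing is the one given in the labels. As a check, the deviations of paired libraries from their group means correlated at -0.14 to 0.09 across genes, and 2 of 9 engulfing libraries correlated best with their own partner among the non-engulfing libraries of the tissue.

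29 gene lists of macrophage functions and of other cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 116 tests of lists and comparisons. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. Changes in list members were also counted adjusted over the list alone. Across genes, the log2 differences of each pair of tissues were correlated, against all swaps of the engulfing label within pairs.

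The design, the gene lists, the rule for named genes and the alternatives, other than those named as added, were chosen before the data were examined. The rule names, per engulfing comparison, up to 8 called genes in each direction that moved alike in every pair and lay above the median level, or the 4 of smallest p in each direction where none is called. It adds up to 4 members of smallest p from every list, 10 genes fixed for their part in engulfment (Il1b, Hmox1, Spic, Cd5l, Mertk, Axl, Abca1, Vcam1, Mki67 and Hba-a1), 8 genes for the difference between tissues and 5 per direction for each tissue comparison. Predicted genes and antigen receptor segments were left out by the rule, and some genes that it names are not reported here.

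Alternatives left out 1 pair or library at a time, took batch 1 alone, dropped the pair block, fitted each tissue alone, changed the pseudocount, filter, threshold, weights and trend, or used quantile normalization. Tests on the recovered reads (edgeR 4.0.16 with its default filter, TMM, median-of-ratios and total scaling; DESeq2 1.42.0; limma-voom with and without quality weights) and scaling by the plain library total were added after seeing the data. Every library was also thinned to the reads of the smallest. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the tables and plots.

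The steps were tested on simulated data: reads for 12774 genes with the real means, library sizes and estimated dispersion (common dispersion 1.57) and 200 changed genes. In the bone marrow comparison limma called 0, 3 and 8 of the 67, 67 and 66 genes changed 2-, 4- and 8-fold, with 0 false calls. There edgeR called 0, 1 and 6 with 0 false calls, limma-voom 0, 3 and 6 with 17 false calls, and DESeq2 5, 13 and 24 with 390 false calls. For 8-fold changes limma called 0 in spleen, 10 in intestine, 20 in the mean over tissues and 0 in the difference between tissues. At a twentieth of that dispersion limma called 61 of the 66 genes changed 8-fold in the bone marrow comparison. A list of 38 genes raised 2-fold there gave a camera adjusted p of 2.13e-14 and, with an estimated correlation, 0.00825, with 0 of 114 other list tests called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls lists of correlated genes falsely.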

Results

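Gene expression was profiled in macrophages that had taken up cells of a parabiotic partner and in macrophages of the same tissue that had not. The partner mice carried DsRed, a red fluorescent protein, and the labels call macrophages that had acquired it engulfing. Spleen and intestine gave sample pairs of replicates 1, 2 and 4, and bone marrow of replicates 1, 3 and 4. In that order, the non-engulfing libraries held 6.66, 11.4 and 20.8 M recovered reads in spleen, 5.88, 6.09 and 40.8 M in bone marrow and 7.78, 8.53 and 34.1 M in intestine. The engulfing libraries held 8.48, 10.04 and 29.5 M in spleen, 4.31, 5.02 and 22.8 M in bone marrow and 4.90, 4.56 and 11.8 M in intestine. Depth followed the library batch, with 4.31 to 11.4 M reads in batch 1 and 11.8 to 40.8 M in batch 2. Between 7458 and 12995 of 14215 genes had at least 1 read, and 8.58% to 47.5% of genes stood at 0 in a library. Engulfing libraries detected more genes than their partner in spleen (by 789, 576 and 441). Their difference from the partner was -2388, -2410 and -2019 genes in bone marrow and -867, -630 and -1955 in intestine. Mitochondrially encoded genes took 10.5% to 23.6% of the signal.

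**Figure D1:**
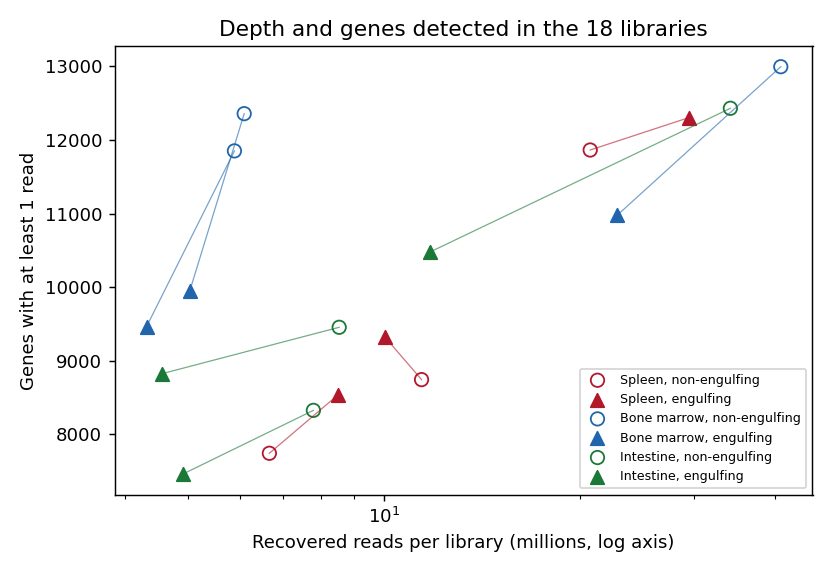
Recovered reads per library (M, log axis) against the number of genes with at least 1 read, for the 18 libraries. Lines join the pairs, filled triangles are engulfing and open circles non-engulfing libraries; in bone marrow the engulfing library of replicate 4 detected 10976 genes and its partner 12995.

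In spleen, the list of red pulp and resident macrophage identity was not called between engulfing and non-engulfing macrophages (median log2 difference 0.05, camera adjusted p = 0.860). Vcam1, an adhesion molecule of red pulp macrophages, stood at 7589 ± 1586 in non-engulfing and 6803 ± 1818 in engulfing libraries (signal, mean ± SD, n = 3). The heme oxygenase gene Hmox1 stood at 1483 ± 395 and 1665 ± 110.2, and Spic, a transcription factor of iron-recycling macrophages, at 692 ± 318 and 659 ± 143. The log2 difference was 0.0031 ± 0.53 for Axl and -0.13 ± 0.57 for Mertk, receptor kinases that bind dying cells. It was 0.35 ± 1.10 for Cd5l, 0.23 ± 0.40 for the cholesterol exporter Abca1 and -0.75 ± 0.55 for the cytokine gene Il1b.

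The genes of smallest p in spleen were higher or lower in all 3 pairs but did not pass. On the higher side stood Wdr61, from 1.15 ± 2.00 to 36.9 ± 13.9 (log2 difference 4.47 ± 0.80, limma adjusted p = 0.570), and Dpy19l3, Myh10 and Sugt1 at 4.09, 4.00 and 3.93. On the lower side stood Nr4a1, an immediate early nuclear receptor, at -2.20 ± 0.58 with pair values -2.20, -1.94 and -2.47. C1galt1, Cuedc2 and the ribosomal protein gene Rps12 stood at -4.41, -4.22 and -3.66, each with adjusted p 1.00. Wdr61 overlaps Dnaja4 in the annotation, and Rps12 holds small nucleolar RNA genes. Hba-a1, a hemoglobin gene, went both ways, with pair values -2.29, 8.91 and -0.53, and the proliferation gene Mki67 stood at 0.12 ± 1.28.

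T and NK cell genes were the 1 list called in spleen, lower in engulfing macrophages (camera adjusted p = 0.0414, median log2 difference -0.34). The adjusted p = 0.757 with an estimated correlation, and the call was lost at equal reads (adjusted p = 0.0651 after thinning every library to 4.31 M reads). Of its 23 members 16 lay below 0, and 0 were called adjusted over the list alone. Cd2, Cd8a and Thy1 stood at -2.57, -2.16 and -2.22, and the T cell receptor component Cd3d at 1.70. 5 members had no read in a whole group, and the median was -1.13 with these at the bound that 3 reads over the group give. The pair medians were 0.00, 0.00 and -0.02.

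With limma, 0 genes passed in spleen, where 628 had an unadjusted p under 0.05 against 711 given by chance; edgeR called 5 (246 at an unadjusted p under 0.05 against 639 by chance), DESeq2 374 and limma-voom 44. The genes called by edgeR were Gm10801, Gm10717, Hspa1a, Antxr2 and Bgn, which fall outside the rule and were chosen after their values were seen. The call of the T and NK cell list was lost without any 1 spleen replicate (adjusted p = 0.0607, 0.269 and 0.0673 without replicates 1, 2 and 4), and also without bone marrow replicate 4 (0.0704) or intestine replicates 1, 2 or 4 (0.0673, 0.0573 and 0.0668), which share the estimate of spread.

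In bone marrow, lists of lysosome, iron handling and resident macrophage genes were called higher in engulfing macrophages, and lists of ribosomal proteins and of T and NK cells were called lower. The adjusted p = 0.693, 0.554, 0.630, 0.554 and 0.757 with an estimated correlation, at which none of these calls holds. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), the scavenger receptor for hemoglobin bound to haptoglobin, stood at 937 ± 649.7 in non-engulfing and 4867 ± 1285 in engulfing libraries. Its log2 difference was 2.63 ± 0.43, with pair values 1.09, 2.58 and 4.21. The mannose receptor Mrc1 went from 1657 ± 1391 to 4569 ± 793 (1.78 ± 0.38), transferrin, Trf, from 807 ± 699 to 2127 ± 211 (1.73 ± 0.37), and Lars2 stood at 1.71 ± 0.31. On the lower side, Cd300e, a receptor of monocytes, went from 110.4 ± 72.0 to 5.86 ± 9.84 (-5.04 ± 0.77), and the fractalkine receptor Cx3cr1 from 117 ± 45.1 to 7.34 ± 8.29 (-4.22 ± 0.83). Cx3cr1 overlaps other genes in the annotation.

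With limma none of these genes passed: the adjusted p was 0.125 for Cd163 and Cd300e and 0.180 for Cx3cr1. On the recovered reads edgeR called Cd163 (adjusted p = 1.23e-04, 2.46e-07 to 0.657 over the alternatives), Cd300e (1.68e-05, 1.71e-10 to 0.657) and Cx3cr1 (0.00102, 1.85e-04 to 0.657), with Mrc1, Trf and Lars2. Ncr1, a receptor of NK cells, had 1 read in the engulfing libraries against 1117 in the non-engulfing ones, a ratio of 681 (95% interval 122 to 26926), with limma adjusted p = 0.125. Bcl2, which opposes cell death, stood at -3.74 ± 0.83 and the ATP synthase gene Atp5k at -2.66 ± 0.56, lower in all 3 pairs.

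8 lists were called higher in bone marrow engulfing macrophages. The lysosome list had a median log2 difference of 0.55 (camera adjusted p = 1.60e-11), with 29 of 38 members above 0, 7 of them at an unadjusted p under 0.05 and 0 called over all genes or adjusted over the list alone. Its proteases Ctsd and Ctsb stood at 1.42 ± 0.47 and 1.18 ± 0.40. Red pulp and resident macrophage identity had a median of 0.96 (adjusted p = 2.37e-09), 14 of 17 above 0 and 0 called adjusted over the list alone, with Vcam1, Itgad and Fcna at 1.86 ± 0.59, 2.65 ± 0.94 and 1.75 ± 0.63 and Spic at 0.96 ± 0.69. Heme and iron handling had a median of 0.64 (adjusted p = 3.75e-08). Of its 17 members 13 lay above 0 and 3 were called adjusted over the list alone. The iron exporter Slc40a1 stood at 1.87 ± 0.55 and Hmox1 at 1.92 ± 0.64. The adjusted p = 0.693, 0.630 and 0.554 with an estimated correlation for these 3 lists.

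Phagocytic receptors and bridging molecules had a median of 0.23 (adjusted p = 2.50e-06, 20 of 33 above 0), and LXR target genes a median of 0.47 (adjusted p = 1.36e-05, 14 of 18). The adjusted p = 0.554 with an estimated correlation for both lists, and 0 members of either were called adjusted over the list alone. Among them Axl stood at 1.79 ± 0.53, Mertk at 1.49 ± 0.57, the phosphatidylserine receptor Timd4 at 2.15 ± 0.69, the engulfment receptor Lrp1 at 1.44 ± 0.48 and the integrin Itgb5 at 1.67 ± 0.48. The cholesterol exporter Abca1 went from 358 ± 202 to 943 ± 288, its relative Abcg1 stood at 1.05 ± 0.40, lipoprotein lipase, Lpl, at 1.64 ± 0.54 and Cd5l at 2.16 ± 1.10. Type I interferon response (adjusted p = 0.0205, median 0.37) and anti-inflammatory and tissue repair genes (adjusted p = 0.0228, median 0.33) were called with mixed members. In the latter Igf1 stood at 1.35 ± 0.41 and Spp1 had 1 read in the engulfing libraries, a ratio of 491 (95% interval 88.0 to 19436) in the other direction. The adjusted p = 0.711 and 0.757 with an estimated correlation. Mitochondrially encoded transcripts had a median of 0.29 (adjusted p = 6.46e-04), which flips to -0.06 under quantile normalization, and the adjusted p = 0.757 with an estimated correlation.

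Ribosomal protein genes, part of the translation machinery, were called lower in bone marrow, with a median of -0.75 and 37 of 38 members below 0 (adjusted p = 9.39e-06). The pair medians were -0.07, -0.75 and -1.19 in replicates 1, 3 and 4, against a median of all genes in replicate 1 of -0.07, and the call was lost without replicate 4 (adjusted p = 0.0830). Rps9 stood at -0.93 ± 0.26 and Rpl4 at -0.79 ± 0.26, and 0 members were called adjusted over the list alone. Reads of these genes can be shared with pseudogene copies. T and NK cell genes were called lower (adjusted p = 0.0278, median -0.68, -0.86 with 4 members at their bound, -0.02 under quantile normalization), with 1 member, Ncr1, called adjusted over the list alone. The NK receptor Klrd1 stood at -3.21 ± 0.93. The adjusted p = 0.554 and 0.757 with an estimated correlation. The median of all genes was -0.40 in bone marrow with the deposited scaling and -0.0045 with quantile normalization, and the list tests compare each list with the other genes. Il1b stood at -1.47 ± 0.55, Mki67 at -0.71 ± 1.28 and Hba-a1 at -0.23 ± 1.87.

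With limma, 0 genes passed in bone marrow, where 1218 (242 higher, 976 lower) had an unadjusted p under 0.05 against 711 given by chance; edgeR called 11 (366 at an unadjusted p under 0.05, 169 higher and 197 lower, against 639 by chance), DESeq2 207, limma-voom 566, and limma without the pair block 25, with 65 genes called when replicate 1 was left out and 27 when replicate 4 was. In replicates 1, 3 and 4 the pair median was -0.44, 0.81 and 1.22 for lysosome and -0.40, 1.24 and 2.59 for red pulp identity (0.36 in batch 1 and 2.59 in batch 2), above 0 in replicates 3 and 4 only. It was -0.24, -0.14 and 1.69 for anti-inflammatory genes, above 0 in replicate 4 only, and 0.08, 0.15 and 0.68 for mitochondrially encoded transcripts. Without replicate 4 the count of called lists was 2 in place of 10. Of 10 splits of the bone marrow libraries, 1, the real one, reached 1218 genes at an unadjusted p under 0.05 (highest other 1128). So few splits cannot exclude chance.

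In the intestine, the list of MHC class II genes, whose products present antigen to CD4 T cells, was called lower in engulfing macrophages, and Cd163 stood higher without passing. The adjusted p = 0.554 with an estimated correlation for this list. H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) stood at 5146 ± 1565 in non-engulfing and 1602 ± 337 in engulfing libraries (log2 difference -1.66 ± 0.38). H2-Aa stood at -1.46 ± 0.46, H2-Ab1 at -1.46 ± 0.46 and the invariant chain Cd74 at -1.26 ± 0.45, lower in all 3 pairs. The integrin Itgax (CD11c), of dendritic cells and intestinal macrophages, went from 380.2 ± 122 to 61.6 ± 8.58 (-2.56 ± 0.64). Cd163 went from 496 ± 213 to 2495 ± 1593, with pair values 2.16, 1.99 and 2.55.

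The MHC class II list was called lower (camera adjusted p = 7.08e-05, median -1.46), with 14 of 15 members below 0, 8 of them at an unadjusted p under 0.05 and 3 called adjusted over the list alone. Its pair medians were -1.23, -1.13 and -1.42 (-1.26 in batch 1 and -1.42 in batch 2). Genes of intestinal macrophage identity were called lower (adjusted p = 0.00832, median -1.35, -1.47 with 1 member at its bound), with 11 of 14 members below 0 and 1 called adjusted over the list alone. Within this list, the tetraspanins Cd81 and Cd9 stood at -1.21 ± 0.45 and -1.73 ± 0.65 and the collagenase Mmp13 at -2.24 ± 0.92. Cholesterol biosynthesis was called lower (adjusted p = 0.0201, median -0.86), with 22 of 24 members below 0 and 0 called adjusted over the list alone. The enzymes Idi1 and Fdps stood at -2.85 ± 0.92 and -4.39 ± 1.48, and Mvd had no read in the engulfing libraries, at least 42.9-fold lower if 3 reads over the group are taken as the limit. Genes of stromal, endothelial and smooth muscle cells were called higher (adjusted p = 0.00178, median 0.78), with 19 of 20 above 0 but 0 called adjusted over the list alone. Their pair values varied, 7.76, -0.13 and 1.82 for the collagen gene Col1a1. The adjusted p = 0.554 with an estimated correlation for each of these 4 lists.

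The genes of smallest p in the intestine were Vopp1 (-5.36 ± 0.67, limma adjusted p = 0.0608), Asb2 (-5.41 ± 0.85) and Smarcd2 (-4.53 ± 0.74) on the lower side. With them stood Trp53inp1, a p53 target, which had 1 read in the engulfing libraries against 1486, a ratio of 625 (95% interval 112 to 24701) with adjusted p = 0.0608. Higher were the lectin Cd209b, from 0.386 ± 0.669 to 35.3 ± 23.6 (4.63 ± 0.63, adjusted p = 0.0608), the microfibril gene Mfap5 (4.05 ± 0.58) and Rad54l2 (4.28 ± 0.87). On the recovered reads edgeR called Cd163 (adjusted p = 5.14e-04, 1.80e-04 to 0.719 over the alternatives), H2-Eb1 (0.0179, 3.01e-05 to 0.719) and Vopp1 (0.00123, 3.42e-10 to 0.719), which overlap Gm20513 and Lancl2 in the last 2 cases, with Trp53inp1, Asb2 and Rps7. Rps7 stood at -3.48 ± 0.68. Axl stood at -1.69 ± 0.53, lower in all 3 pairs, while Mertk stood at 0.65 ± 0.57, Abca1 at 0.56 ± 0.40, Hmox1 at 0.49 ± 0.64 and Vcam1 at 0.10 ± 0.59. Il1b stood at -1.08 ± 0.55, Spic at 71.9 ± 22.2 in non-engulfing and 39.5 ± 37.8 in engulfing libraries, and the log2 difference was -2.28 ± 1.10 for Cd5l, -1.93 ± 1.28 for Mki67 and -0.65 ± 1.87 for Hba-a1.

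With limma, 0 genes passed in the intestine, where 1261 (396 higher, 865 lower) had an unadjusted p under 0.05 against 711 given by chance; edgeR called 21 (575 at an unadjusted p under 0.05 against 639 by chance), DESeq2 723, limma-voom 89, and limma without the pair block 26. Of 10 splits of the intestine libraries, the real one included, 5 gave at least 1261 genes at an unadjusted p under 0.05 (highest other 2536). Among the 4 that part every pair only the real one did, and the others gave 938 to 1014. Without replicates 1, 2 and 4 in turn limma called 1, 9 and 21 genes, and without replicate 4 the count of called lists was 2 in place of 4. The engulfing intestine library of replicate 1 stood apart on the third principal component (8.78% of the variance), at 174 against -94.4 to 37.7 in the others. Without its pair cholesterol biosynthesis was no longer called (adjusted p = 0.0651), while the other 3 lists were.

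**Figure D2:**
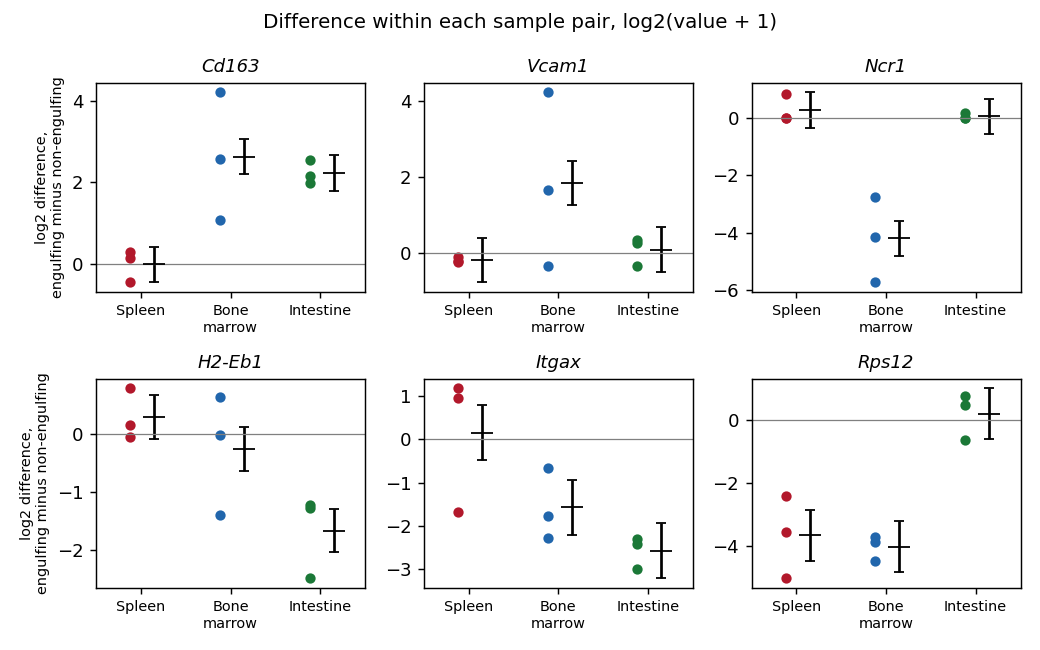
Log2 difference of signal + 1, engulfing minus non-engulfing, per sample pair (points) with the fitted value and its standard error (bars) for 6 genes in the 3 tissues. Cd163 lies at -0.01 in spleen (shown after its value there was seen), 2.63 in bone marrow and 2.23 in intestine.

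Averaged over the tissues, lists of iron handling, lysosome and red pulp genes were called higher in engulfing macrophages, and lists of cholesterol synthesis and ribosomal proteins were called lower. The adjusted p = 0.711, 0.757, 0.780, 0.554 and 0.693 with an estimated correlation. In spleen, bone marrow and intestine taken apart the list median was 0.09, 0.55 and -0.17 for lysosome and 0.05, 0.96 and -0.38 for red pulp identity. In the same order it was 0.0059, 0.64 and 0.14 for iron handling and 0.03, -0.75 and -0.15 for ribosomal proteins. For cholesterol synthesis it was -0.29, -0.90 and -0.86. Cd163 had the smallest p of all genes and stood at 1.62 ± 0.25, above 0 in 8 of 9 pairs, with limma adjusted p = 0.296 and edgeR adjusted p = 6.89e-06 (1.41e-06 to 0.796 over the alternatives). Wwp1, a ubiquitin ligase, stood at 0.74 ± 0.19, the thromboxane synthase gene Tbxas1 at 0.89 ± 0.27 and Ehd1, of endosomal recycling, at 0.65 ± 0.20, above 0 in all 9 pairs. Nlrp3, an inflammasome sensor, stood at -2.51 ± 0.70, Cd244a at -2.35 ± 0.62, and Galnt7 at -1.88 ± 0.43, below 0 in all 9 pairs, and Rps7 stood at -1.71 ± 0.39. The adjusted p = 0.645 for each of these 7 genes other than Cd163. Abca1 stood at 0.76 ± 0.23, Il1b at -1.10 ± 0.32, Hmox1 at 0.87 ± 0.37, Mertk at 0.67 ± 0.33 and Vcam1 at 0.60 ± 0.34. Axl stood at 0.03 ± 0.31, Spic at -0.08 ± 0.40, Cd5l at 0.07 ± 0.64, Mki67 at -0.84 ± 0.74 and Hba-a1 at 0.38 ± 1.08. Il1b overlaps the antisense gene Il1bos.

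Called higher over the tissues were heme and iron handling (adjusted p = 9.45e-05, median 0.25, 13 of 17 members above 0), lysosome (adjusted p = 1.83e-04, 0.20, 29 of 38), red pulp identity (adjusted p = 0.00808, 0.28, 13 of 17) and mitochondrially encoded transcripts (adjusted p = 0.00861, 0.16, 13 of 13; -0.14 in batch 1 and 0.69 in batch 2). Slc40a1 stood at 0.88 ± 0.32, Trf at 0.61 ± 0.21, Fcna at 1.06 ± 0.36, Ctsd at 0.63 ± 0.27, the lysosomal nuclease Dnase2a at 1.00 ± 0.45 and Cd68 at 0.46 ± 0.21. Called lower were ribosomal proteins (adjusted p = 6.50e-04, -0.28, 34 of 38 below 0), cholesterol biosynthesis (adjusted p = 0.0271, -0.62, 22 of 24) and T and NK cells (adjusted p = 0.0417, -0.51, 19 of 23; -0.77 with genes without reads at their bound). The call of T and NK cells was lost at equal reads (adjusted p = 0.0638). Fdps and Idi1 stood at -2.59 ± 0.85 and -1.26 ± 0.53, and Rps9 and Rpl4 at -0.53 ± 0.15 and -0.39 ± 0.15. Adjusted over the list alone, 1 gene of heme and iron handling, 1 of ribosomal proteins and 0 of the other called lists passed. The adjusted p = 0.711, 0.757, 0.780, 0.780, 0.693, 0.554 and 0.757 with an estimated correlation for these lists in the order given. The median of all genes was -0.15, and 0.0026 under quantile normalization.

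With limma, 0 genes passed for the mean, where 980 had an unadjusted p under 0.05 against 711 given by chance; edgeR called 17 (502 at an unadjusted p under 0.05 against 639 by chance), DESeq2 354 and limma-voom 80. Without spleen replicate 1 limma called 2 genes and without bone marrow replicate 1 it called 1. Without 1 pair the count of called lists ran from 2 (bone marrow replicate 4; 3 without intestine replicate 4) to 10 (bone marrow or spleen replicate 1) in place of 7.

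The engulfing effects of the tissues were nearly uncorrelated across genes, which are not independent replicates. How well the effects repeat within a tissue was not measured. Noise draws a correlation toward 0, so low values do not show that the tissues respond differently. Pearson's r was -0.00511 between spleen and bone marrow, 0.0134 between spleen and intestine and 0.0294 between bone marrow and intestine. Spearman's rho was -0.0120, 0.0149 and 0.0242. Of the 16 swaps of the engulfing label within pairs, 12, 6 and 2 gave an r as large. Tested gene by gene, the genes that differed most between tissues included Ncr1, with log2 differences of 0.28 in spleen, -4.19 in bone marrow and 0.06 in intestine. Trp53inp1, Vopp1 and Slc7a4 were lowest in the intestine (-5.25, -5.36 and -3.63) and Cd209b highest there (4.63), while Fut7 stood at -3.36 in bone marrow. Wdr61 and Mrps35 stood at 4.47 and 2.95 in spleen and -0.93 and -3.12 in bone marrow. These 8 genes had adjusted p = 0.576 with limma, which called 0 genes, with 947 at an unadjusted p under 0.05 against 711 given by chance; edgeR called 18 (442 at an unadjusted p under 0.05 against 639 by chance), DESeq2 37, limma-voom 242. Without bone marrow replicate 1 limma called 3.

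Among non-engulfing macrophages, limma called genes between each 2 of the 3 tissues. Spleen macrophages carried more Adamdec1, a secreted metalloprotease, than bone marrow macrophages, 357 ± 99.7 against 0.189 ± 0.327 (log2 difference 8.23 ± 0.57, limma adjusted p = 0.00297). The inhibitory receptor Siglece (3.96 ± 0.39), the adhesion receptor Cd44 (2.83 ± 0.26) and Lars2 (2.31 ± 0.22) were also higher in spleen. The chemokine gene Ccl9 (-6.74 ± 0.68) and Cx3cr1 (-5.75 ± 0.57) were lower there, with adjusted p = 0.0114 and 0.0109. These 6 genes were all that limma called in this comparison (4 higher, 2 lower).

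Compared with bone marrow, Lyve1, a hyaluronan receptor, was higher in intestinal macrophages (248 ± 35.7 in intestine, and 1 read over the bone marrow libraries, a ratio of 10988 (95% interval 1972 to 434050), adjusted p = 0.0226), as were the endocytic adaptor Dab2 (7.64 ± 1.27), Adamdec1 (7.51 ± 0.57) and Ecm1 (7.29 ± 1.09). Spint1 had no read in the bone marrow libraries and was at least 2354-fold higher in intestine. Lower in intestine were the globin gene Hbb-bt (-9.67 ± 1.15), Chil3 (-7.93 ± 1.16), Ear2 (-7.86 ± 0.54) and the neutrophil gene S100a9 (-7.62 ± 0.86). Myeloperoxidase, Mpo, of granulocyte precursors, had no read in intestine and was at least 5428-fold lower there. Whether reads of Mpo, S100a9 and Hbb-bt came from macrophages or from other cells in the samples was not tested. Compared with spleen, Dab2 (10.62 ± 1.27), the clotting factor gene F13a1 (10.35 ± 0.68), Cx3cr1 (9.52 ± 0.57) and the scavenger receptor Stab1 (9.46 ± 1.37) were higher in intestine. The integrin Itgad (0.402 ± 0.151 in intestine, 1052 ± 448 in spleen), Ccr3 (-9.28 ± 0.90), Cd300e, Slpi (-8.65 ± 1.02) and Hbb-bt (-8.65 ± 1.15) were lower in intestine. With 1 read in intestine, Cd300e differed by a ratio of 25205 (95% interval 4523 to 995590). Limma called 86 genes between intestine and bone marrow (44 higher, 42 lower) and 236 between intestine and spleen (140 higher, 96 lower).

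The tissue counts depend on the model and on single libraries. The non-engulfing libraries also differed in genes detected, 12401 ± 573 in bone marrow, 10070 ± 2121 in intestine and 9449 ± 2149 in spleen (mean ± SD). With the replicate number as a block, limma called 0 genes between spleen and bone marrow, 0 between intestine and bone marrow and 7 between intestine and spleen. Leaving out bone marrow replicate 1 or 4 gave 279 or 439 genes between spleen and bone marrow in place of 6, and 446 or 648 between intestine and bone marrow in place of 86, while leaving out other libraries lowered the counts. The lowest were 0 between spleen and bone marrow (without spleen or intestine replicate 4), 0 between intestine and bone marrow (without bone marrow replicate 3) and 8 between intestine and spleen (without spleen replicate 4).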

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

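The list tests of the difference between tissues and the tests of depth, of other cells, of library quality and of single pairs were chosen after the results were seen. For each list, the engulfing effects of 2 tissues were compared with camera on the difference of the effects (87 tests), and 22 differences passed, with adjusted p from 3.97e-06 to 0.0410 at the preset correlation and from 0.540 to 0.680 with an estimated correlation, at which none holds. Values below are medians of log2 differences over list members.

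At the preset correlation only, lists of macrophage genes were called as different between bone marrow and both other tissues. The engulfing effect in bone marrow exceeded that in spleen for phagocytic receptors (0.55), LXR target genes (0.59), lysosome (0.55), heme and iron handling (0.68), red pulp identity (0.95) and mitochondrially encoded transcripts (0.22). It was lower than in spleen for ribosomal proteins (-0.84). The effect in intestine was below that in bone marrow for phagocytic receptors (-0.83), LXR target genes (-1.19), lysosome (-0.84), heme and iron handling (-0.58), red pulp identity (-1.56), type I interferon response (-0.95) and MHC class II (-1.52). It was above that in bone marrow for ribosomal proteins (0.60), T and NK cells (0.82) and stromal cells (1.68). The last 2 rest on few members with reads, since 17 of 23 T and NK genes had no read in a whole group in intestine and 10 of 20 stromal genes in bone marrow.

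Between intestine and spleen, the list of antigen presentation genes was called as different, again at the preset correlation only. The intestinal effect was lower for MHC class II (-1.70), intestinal macrophage identity (-1.57) and type I interferon response (-1.13), and higher for monocytes (0.85) and stromal cells (0.76; 8 of 20 had no read in a whole group in spleen).

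The 5 macrophage lists higher in bone marrow engulfing libraries (lysosome, red pulp identity, heme and iron handling, phagocytic receptors and LXR target genes) were weighed against technical explanations. A difference in depth cannot be judged by thinning here, since the values are scaled to the library total, which thinning leaves nearly unchanged. After every library was thinned to 4.31 M reads, 5 of the 5 were still called. For lysosome the camera adjusted p was 1.60e-11 before thinning and 2.06e-11 after. A lower share of macrophages in the non-engulfing samples cannot be told apart. It would lower the markers of whichever other cells those samples held, and these need not move alike. Neutrophil minus T and NK list medians differed by 1.36 (SE 0.803, 3 pairs), within the spread, and this difference cannot decide the question. In replicates 1, 3 and 4 the medians were 0.38, -1.32 and 1.45 for neutrophils, 0.00, -2.06 and -1.50 for T and NK cells, -0.29, -0.85 and -0.42 for monocytes, -0.72, -0.47 and -1.24 for dendritic cells, -1.50, -1.30 and -0.09 for mast cells, basophils and eosinophils, 1.93, -0.82 and -0.86 for megakaryocytes and 0.03, -0.30 and -1.23 for erythroid cells. Dependence on 1 pair alone cannot be told apart. Without replicate 4, lysosome and heme and iron handling were still called (adjusted p = 0.00777 and 0.00400), and red pulp identity, phagocytic receptors and LXR target genes were not (0.0944, 0.0704 and 0.116). Of the 2 pairs left, replicate 3 carries these values: in replicates 1 and 3 the medians were -0.44 and 0.81 for lysosome, -0.13 and 1.00 for heme and iron handling, -0.40 and 1.24 for red pulp identity, -0.14 and 0.43 for phagocytic receptors and 0.0024 and 0.32 for LXR target genes. Lower library quality cannot be told apart: in 3 of 3 bone marrow pairs the engulfing library had fewer genes detected (a difference of -2388, -2410 and -2019) and a higher mitochondrial share (15.2% against 11.8%, 11.4% against 10.8%, 17.9% against 13.9%), but 4 of the 5 lists lay below 0 in replicate 1. A difference between macrophages that engulf and those that do not stays open and was not tested apart from these.

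Genes detected differed between tissues in opposite directions, and this difference was not tested. Engulfing libraries detected more genes than their partners in all 3 spleen pairs and fewer in all 6 pairs of bone marrow and intestine, so that the effect differed by -2874 genes between bone marrow and spleen and by -1753 between intestine and spleen. A difference in depth is argued against, since 9 of 9 pairs kept their direction at equal reads.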

How the results depend on the processing

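Tests on recovered reads, scaling by the library total and list tests with another scaling, pseudocount, filter or voom weights were chosen after seeing the data; the other tests were planned. Counts of called genes follow in the order spleen, bone marrow, intestine, mean over tissues and difference between tissues, where limma called 0 in each, and then spleen against bone marrow (6), intestine against bone marrow (86) and intestine against spleen (236). The cause of a change was not tested unless stated.

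edgeR called 5, 11, 21, 17 and 18, and 29 for spleen against bone marrow. With median-of-ratios scaling it called 5, 11, 17, 16 and 12, then 29, and with library totals 5, 10, 18, 15 and 12, then 28. DESeq2 called 374, 207, 723, 354 and 37, then 1286, 1367 and 1820. In simulated data DESeq2 made 390 false calls. limma-voom called 44, 566, 89, 80 and 242, then 606, 966 and 564, and with quality weights 57, 528, 93, 95 and 227, then 837 and 1215.

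Without the pair block limma called 25 genes in bone marrow and 26 in intestine. Testing only genes with a mean above the median gave 8 in intestine, 5 in the mean and 95, 268 and 373 between tissues, where fewer genes are tested. In intestine a pseudocount of 0.1 gave 1, quantile normalization 2 and array weights 1. Spleen against bone marrow and intestine against bone marrow gave 22 and 192 with quantile normalization, 11 and 561 with array weights, and 189 and 402 without trend. For the 3 tissue comparisons, the replicate number as a block gave 0, 0 and 7, all 18 libraries with a pair correlation (0.0486) gave 219, 554 and 409, and adjusted p under 0.01 gave 1, 4 and 14. Intestine against bone marrow gave 457 without the batch term and 55 with library totals.

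Leaving out 1 pair gave 0 to 0 genes in spleen, 0 to 65 in bone marrow (65 without replicate 1, 27 without replicate 4), 0 to 21 in intestine (1, 9 and 21 without replicates 1, 2 and 4), 0 to 2 in the mean (2 without spleen replicate 1, 1 without bone marrow replicate 1) and 0 to 3 in the difference between tissues (3 without bone marrow replicate 1). Leaving out 1 library gave 0 to 439 for spleen against bone marrow, 0 to 648 for intestine against bone marrow and 8 to 110 for intestine against spleen. Without bone marrow replicates 1, 3 and 4 the counts were 279, 1, 439 then 446, 0, 648 then 80, 17, 107; without spleen replicates 1, 2 and 4 they were 5, 3, 0 then 41, 33, 11 then 86, 80, 8; without intestine replicates 1, 2 and 4 they were 3, 4, 0 then 59, 2, 1 then 110, 12, 37. Where an arm keeps few libraries, these are assumed to vary like the other groups.

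Of 1, 10, 4 and 7 called lists in spleen, bone marrow, intestine and the mean, an estimated correlation kept 0, 0, 0 and 0, fry called 0, 1, 1 and 1 (cholesterol biosynthesis each time, which camera did not call in bone marrow, adjusted p = 0.584), voom weights 4 in spleen and 10 in intestine, and genes above the median 2 in intestine. Leaving out 1 pair gave 0 to 2, 2 to 12, 2 to 4 and 2 to 10 lists (in bone marrow 2 without replicate 4). Mitochondrially encoded transcripts in bone marrow reversed under quantile normalization (adjusted p = 0.775, 2.00e-09 to 0.936 over the alternatives). The correlation of effects between spleen and bone marrow moved to -0.0353 among genes above the median, and leaving out 1 pair gave -0.0130 to 0.00460, -0.00155 to 0.0213 and 0.0139 to 0.0354 (the lowest of the last without bone marrow replicate 1) for the 3 pairs of tissues. Of the values of named genes under alternatives, 3227 kept their side of the threshold, 211 passed it and 135 no longer passed. A reversal was counted only for genes with an unadjusted p under 0.05 in the main fit, and 0 reversed. Changes of direction in the other genes were not counted. For lists 296 kept their direction and side of the threshold, 99 no longer passed and 1 reversed.

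A test without any filter moves nothing here, since none was applied, nor does dropping the block for the correlation of effects, and the epithelial list had too few members above the median. Depth limits genes with few reads: the smallest library holds 4.31 M reads and 47.5% of genes at 0 in a library is the highest share.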

Other observations

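The tests of satellite-like genes and over other splits of the samples were chosen after the results were seen. Beyond the called lists, genes of dividing cells lay lower in bone marrow engulfing macrophages without passing: the proliferation list had a median of -0.95, with 30 of 30 members below 0 and pair medians of 0.22, -1.07 and -1.92 in replicates 1, 3 and 4 (camera unadjusted p = 0.0233, estimated-correlation adjusted p = 0.757). The erythroid list stood at -0.24 in spleen, -0.68 in bone marrow and 0.02 in intestine (adjusted p = 0.988, 0.763 and 0.667). The neutrophil list stood at -0.11, 0.14 and 0.00 (adjusted p = 0.119, 0.584 and 0.584), the B cell list at 0.00, -0.11 and 0.00 (adjusted p = 0.953, 0.478 and 0.262) and the monocyte list at 0.02, -0.65 and 0.30 (adjusted p = 0.184, 0.793 and 0.0764). Immediate early genes, which also rise when tissue is dissociated, stood at -0.16, -0.65 and -0.05 (adjusted p = 0.115, 0.0956 and 0.810).

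Genes with satellite-like repeats stood higher in engulfing libraries of every pair. The 13 predicted genes whose annotated transcripts hold at least 2 copies of a 12-base motif of major satellite repeats (5 to 13 copies) were summed: reads scaled to the library total (RPM) were higher in engulfing libraries by a mean log2 ratio of 1.85 (SD 1.21, 3.60-fold), in 9 of 9 pairs. The ratio was 2.19 in spleen, 1.68 in bone marrow and 1.67 in intestine, and 1.36 in batch 1 and 2.82 in batch 2. No p is given, since 6 of the 13 had been called by edgeR and prompted the set. The 7 of the 13 that edgeR called in no comparison had a median above 0 in 8 of 9 pairs. These 7 were picked by the same motif as the other 6 and are not an independent check.

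A candidate explanation is that nuclear material or DNA of the engulfed cells, or of dying cells, adds such reads, and this remains a hypothesis since the set was chosen after such genes were seen among those called by edgeR. A difference in depth cannot be judged by thinning, since the values are shares of the library total, which thinning leaves nearly unchanged. After thinning to equal reads 9 of 9 pairs stayed higher. With the deposited scaling 9 of 9 pairs were higher too, so the direction did not depend on the choice between these scalings. Fewer genes detected in engulfing libraries cannot be told apart: the ratio was 2.19 in spleen, where the engulfing libraries detected more genes, but its 3 pairs vary too widely to decide (0.82, 1.03 and 4.72). DNA in the engulfing samples, whose reads would also fall on genes that are not expressed, cannot be told apart, since 6 of 9 pairs had fewer genes detected in the engulfing library and the 3 spleen pairs had more.

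Other splits of the samples show how far chance can be excluded. Within a tissue the 6 libraries make 10 splits, too few for a share under 0.05. With 0 genes called by limma in the real split (628, 1218 and 1261 at an unadjusted p under 0.05; edgeR 5, 11 and 21), 10 of 10 splits called as many in spleen, bone marrow and intestine alike, which a count of 0 fixes beforehand and which says nothing about chance. The highest of the others was 82, 163 and 460, in splits that part 1 pair only and take their effect from that pair, unlike the real split. The other splits that part every pair called at most 0, 0 and 1. At an unadjusted p under 0.05, 6, 1 and 5 of 10 splits gave as many genes as the real one. Splits that part every pair, other than the real one, gave 580 to 630 genes in spleen, 430 to 942 in bone marrow and 938 to 1014 in intestine. The 711 given by chance is 5% of the genes tested, and such splits passed it in bone marrow and intestine. For lists the real count and highest other were 1 and 5 in spleen, 10 and 13 in bone marrow and 4 and 4 in intestine, and 10, 4 and 2 of 10 splits called as many. Among the 4 splits that part every pair, 4, 2 and 1 called as many (highest other 3, 12 and 1).

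For the mean over tissues, 100 drawn splits include the real one. All 100 reach the real count of 0 called genes (highest other 0), which says nothing about chance. 35 called as many lists as the real 7 (highest other 13), so chance is not excluded for the lists. For genes at an unadjusted p under 0.05 with limma, 1 of 100 splits, the real one, reached 980 (highest other 943). This is the smallest share that 100 splits allow. With edgeR 502 genes were at an unadjusted p under 0.05, fewer than the 639 given by chance, so the excess seen with limma was not seen there. The splits were not refitted with edgeR, so chance is not excluded for that test. For the difference between tissues all 100 again reach the real count of 0 (highest other 0). With limma 1 of 100, the real one, reached 947 genes at an unadjusted p under 0.05 (highest other 826). The drawn splits did not keep 1 pair of batch 2 in each tissue, unlike the real one. With edgeR 442 genes were at an unadjusted p under 0.05 against 639 given by chance. The splits were not refitted with edgeR here either, and chance is not excluded for that test. Between non-engulfing tissues 10 splits are again too few: 1, the real one, called as many as the real 6, 86 and 236 genes, and the highest other was 0 in each comparison.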
